A study of Sus scrofa with 11 samples.

How the data were processed

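Total RNA of porcine coronary arteries was measured by paired-end RNA sequencing in 11 libraries, from native vessels (2), stented static (2), stented high-flow (3), high-flow (2) and low-flow (2) cultures. Vessels were flash frozen and RNA was purified on columns with DNase treatment, per the labels' protocols. The authors trimmed reads with Trimmomatic, checked them with FastQC, used the Sscrofa11.1 genome and compared groups with DESeq2, per the submitters' processing notes. The aligner and the annotation release are not given in the sources used here. The deposited values are gene counts per library in 2 tables, joined by gene, whose native columns are identical. The authors' lists of changed genes give log2 fold changes against native and were used only for a check: of 534, 1085, 1098 and 894 listed genes that could be matched for stented static, stented high-flow, high-flow and low-flow, 99.4%, 99.7%, 92.4% and 91.9% were also called here, in the same direction, while 1424, 2655, 1257 and 1082 genes called here were not listed.

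Groups were taken from the labels. The labels carry a d suffix of 3 on both stented static libraries and 7 on stented high-flow replicate 3, and its meaning is not given in the sources used here. Native replicate 2 and stented high-flow replicate 1 share experiment number 25, and whether they came from the same animal is not given either. The tables hold 25880 gene identifiers, 14857 of them with a symbol, and coordinates are RefSeq positions in Sscrofa11.1 matched by symbol. Library totals in units of 1e6 counts were 17.5 and 20.2 in native, 21.9 and 14.2 in stented static, 13.5, 19.7 and 22.2 in stented high-flow, 20.0 and 19.0 in high-flow and 22.8 and 26.8 in low-flow. In single libraries 3 counts correspond to 0.105 to 0.215 CPM. Pearson correlations of log2 CPM between replicates were 0.932 to 0.979. Replicate variance was 53.9 to 180 times the Poisson variance, so the spread between libraries far exceeds counting error.

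Counts were analysed in R 4.3.3 with edgeR 4.0.16, using filterByExpr (15348 genes kept), TMM scaling and the quasi-likelihood F-test in 1 joint fit of the 5 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.126, with 5.02 prior and 6 residual degrees of freedom. Log2 CPM used a prior count of 2. The 7 comparisons set each cultured group against native, stented high-flow against stented static, low-flow against high-flow, and stented high-flow against high-flow. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, with adjustment over the lists of a comparison. The design, the 29 lists, the followed genes and the alternatives listed below were chosen before the data were examined. The alternative without Y-linked genes and the clock and metallothionein lists were chosen after.

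The 29 lists were contractile smooth muscle, synthetic smooth muscle and matricellular, fibrillar collagen and collagen assembly, basement membrane and elastic fibre, matrix proteases and inhibitors, endothelial identity, flow-responsive endothelial, inflammatory cytokines and chemokines, interferon response, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, fatty acid oxidation, cholesterol biosynthesis, oxidative stress and NRF2, unfolded protein and heat shock response, immediate early, TGF-beta and BMP targets, osteochondrogenic, thrombosis and fibrinolysis and mitochondrially encoded genes, and markers of macrophages, lymphocytes, neutrophils and mast cells, adventitial fibroblasts, adipocytes, cardiomyocytes, erythrocytes and platelets, and Schwann and neural cells. Of 609 members 528 were matched. Named genes came from 3 sources per comparison: the 8 largest rises and 8 largest falls among called genes with a symbol, a mean log2 CPM of at least 3 and all libraries of one group above all of the other; up to 4 called members per list with the largest change; and MYH11, ACTA2, CNN1, KLF2, KLF4, NOS3, PECAM1, COL1A1, SPP1 and IL6 in every comparison. MKI67 was also to be followed but no symbol matched it. Where this gave more than could be described, genes kept when single libraries were left out were preferred. AVPR1A and the Y-linked genes were added after their values were seen.

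Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, a robust dispersion, no filter, at least 10 counts in every library, a threshold of 0.01, a replicate block, only the groups compared, only the libraries of one count table, leaving out mitochondrially encoded genes and leaving out each library in turn. The script was tested on simulated data, 10 draws with 200 changed genes per group. At 2-, 4- and 8-fold it recovered 1.41%, 39.7% and 74.2% of changed genes in stented static against native, 3.32%, 50.5% and 75.5% in stented high-flow, 1.93%, 40.8% and 71.7% in high-flow and 2.30%, 37.5% and 74.1% in low-flow. It recovered 5.72%, 57.3% and 81.9% in stented high-flow against stented static, 3.66%, 51.3% and 77.9% in low-flow against high-flow and 6.48%, 60.4% and 81.4% in stented high-flow against high-flow. Of all calls 3.08% to 5.11% were false. In a simulation of high-flow against native camera called a shifted list in 10 of 10 draws and 1 of 280 unshifted lists.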

Results

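RNA sequencing counts were analysed for 11 libraries of porcine coronary artery, made to describe an ex vivo culture model for stent testing. Native arteries gave 2 libraries, and the other 9 came from vessels kept in a bioreactor. The cultured groups were stented vessels held static (2 libraries, stented static), stented vessels under flow (3 libraries, stented high-flow), vessels without a stent under the same marked flow (2 libraries, high-flow) and vessels without a stent under low flow (2 libraries, low-flow). High flow here stands for the stronger of the 2 flow marks in the labels. Expression is given as counts per 1e6 (CPM) on scaled library sizes, as mean ± SD over the libraries of a group, with n = 2 everywhere except stented high-flow, where n = 3. Changes are log2 fold changes ± standard error. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15348 genes, and those of gene lists are from camera. The labels do not say that libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

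The first principal component (44.1% of the variance) set the native libraries apart from the 9 cultured ones, and the second (17.1%) set the stented static libraries, replicate 1 most of all, at one end. Against native, edgeR called 1955 genes in stented static (851 higher, 1104 lower), 3737 in stented high-flow (1599 higher, 2138 lower), 2272 in high-flow (912 higher, 1360 lower) and 1904 in low-flow vessels (772 higher, 1132 lower). A set of 924 genes was called in all 4 comparisons in the same direction, 338 higher and 586 lower, out of 4476 called in at least 1. Independent lists of these sizes would share 1.27 genes, and 20 simulations of unchanged groups against the shared native libraries gave 0. Since the native libraries are common to all 4 comparisons and cannot be split into groups of 2, part of the excess can come from them. Without native replicate 1 the shared set was 297 genes and without native replicate 2 it was 283. Over all genes tested, the covariance of log2 fold changes between pairs of these comparisons was 1.90 to 2.66, and in the simulations it was 0.230 to 0.232.

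**Figure D1:**
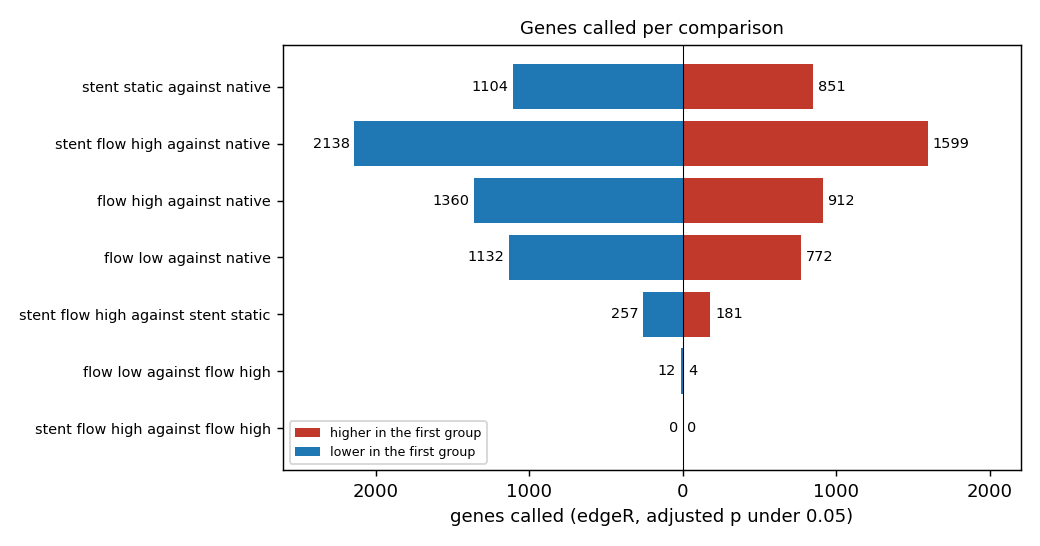
Number of genes called by edgeR (adjusted p under 0.05) in each of the 7 comparisons, with genes higher in the first group to the right (red) and lower to the left (blue). The comparisons with native called 1904 to 3737 genes, and stented high-flow against high-flow called 0.

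The first comparison asked how stented vessels held without flow differed from native arteries. Contractile smooth muscle genes and immediate early genes were lower, while genes of glycolysis and hypoxia, macrophage markers and the haem-degrading enzyme HMOX1 were higher. None of the 13 list calls held with an estimated correlation (adjusted p = 0.214 to 0.495). Smooth muscle myosin heavy chain MYH11 (chromosome 3, 7002667 to 7143093 in Sscrofa11.1) went from 11875 ± 1044 CPM in native to 375 ± 438 CPM, and the transcription factor EGR1 (chromosome 2, 140440829 to 140445302) from 8035 ± 599 to 58.7 ± 9.58 CPM. The lactate dehydrogenase gene LDHA (chromosome 2, 40814163 to 40827284) rose from 65.5 ± 15.5 to 682 ± 97.6 CPM, and GPNMB (chromosome 9, 92037428 to 92071501), a glycoprotein of lipid-laden macrophages, from 5.26 ± 0.533 to 664 ± 277 CPM.

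Of 17 measured contractile genes, 12 fell and 0 rose (1 higher and 14 lower adjusted over the list alone, median log2 fold change -3.51, camera adjusted p = 4.26e-08, or 0.326 with an estimated correlation). The enteric actin gene ACTG2 changed by -6.30 ± 0.95 (edgeR adjusted p = 0.00253) and the myosin light chain MYL9 by -4.82 ± 0.95 (adjusted p = 0.00952). Smooth muscle actin ACTA2 (chromosome 14, 100868145 to 100886732) changed by -4.70 ± 0.98 (adjusted p = 0.0124), calponin CNN1 (chromosome 2, 70183370 to 70190756) by -5.09 ± 1.03 (adjusted p = 0.0110) and MYH11 by -4.98 ± 1.26 (adjusted p = 0.0282). The stented static libraries differed from each other here, with MYH11 at 65.5 CPM in replicate 1 and 685 CPM in replicate 2. MYH11 lost its call without native replicate 1 (edgeR adjusted p = 0.0782), native replicate 2 (0.0957) or stented static replicate 1 (0.101), and ACTA2 and CNN1 lost theirs without native replicate 2 (0.0557 and 0.0509). Without stented static replicate 2 the log2 fold change was -7.50 for MYH11 and -7.67 for ACTA2.

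Immediate early genes, which are induced within minutes by stress and growth factors, fell in 12 of 18 cases and rose in 0 (1 higher and 15 lower adjusted over the list alone, median log2 fold change -3.21, camera adjusted p = 3.19e-11, or 0.214 with an estimated correlation). FOSB (chromosome 6, 51836780 to 51844531) changed by -9.13 ± 1.07, EGR1 by -7.10 ± 0.66, FOS by -6.35 ± 0.86 and the nuclear receptor NR4A1 by -6.38 ± 0.56 (edgeR adjusted p = 0.000280 to 0.00162). The chemokine CXCL2 changed by -6.69 ± 0.80. The flow-induced endothelial factor KLF4 (chromosome 1, 248604817 to 248609574) changed by -3.05 ± 0.36 to a level of 53.7 ± 4.80 CPM. KLF2 (chromosome 2, 61270733 to 61273037), its close relative, changed by -2.33 ± 0.51 (adjusted p = 0.0157), a call lost without native replicate 1 (0.0633) or native replicate 2 (0.0798), and its log2 fold change was -3.54 without stented static replicate 1.

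Hypoxia and glycolysis genes rose in 14 of 20 cases and fell in 0 (14 higher and 1 lower adjusted over the list alone, median log2 fold change 1.83, camera adjusted p = 5.52e-09, or 0.244 with an estimated correlation). Carbonic anhydrase CA12 (chromosome 1, 108649277 to 108710658) changed by 4.41 ± 0.34, hexokinase HK2 by 4.16 ± 0.52 and LDHA by 3.38 ± 0.42 (edgeR adjusted p = 0.000217 to 0.00106). The lactate exporter SLC16A3 changed by 7.91 ± 0.86, uridine phosphorylase UPP1 by 7.63 ± 0.91 and the hypoxia-induced complex subunit paralogue NDUFA4L2 by 6.15 ± 0.64. In the oxidative stress list 6 of 18 genes rose and 0 fell (12 higher and 1 lower adjusted over the list alone, median log2 fold change 1.13, camera adjusted p = 0.000181, or 0.244 with an estimated correlation). HMOX1 changed by 4.95 ± 0.48. Of 20 unfolded protein and heat shock genes 5 rose and 1 fell (10 higher and 1 lower adjusted over the list alone, median log2 fold change 0.80, camera adjusted p = 0.000435, or 0.378 with an estimated correlation). Of 23 cholesterol synthesis genes 7 rose and 1 fell (10 higher and 1 lower adjusted over the list alone, median log2 fold change 1.39, camera adjusted p = 0.000358, or 0.495 with an estimated correlation). All 13 mitochondrially encoded genes were measured, of which 11 fell and 0 rose (0 higher and 13 lower adjusted over the list alone, median log2 fold change -2.36, camera adjusted p = 2.27e-09, or 0.255 with an estimated correlation). Their share of all counts was 10.3% and 10.7% in the native libraries and 3.19% and 4.65% in the stented static ones. Cytochrome b, CYTB, changed by -3.60 ± 0.43 and ND1 by -2.67 ± 0.38.

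Matrix proteases and their inhibitors rose in 9 of 19 cases and fell in 1 (10 higher and 2 lower adjusted over the list alone, median log2 fold change 1.68, camera adjusted p = 0.000570, or 0.259 with an estimated correlation). The gelatinase MMP9 (chromosome 17, 48179690 to 48186782) had 3 counts over both native libraries, against which stented static vessels had 201 (95% counting interval 68.4 to 976) times the CPM. Such intervals, and limits set at 3 counts over a group, cover counting error only. The urokinase receptor PLAUR rose by 3.23 ± 0.41 and the osteogenic transcription factor RUNX2 (chromosome 7, 40106581 to 40353304) by 4.96 ± 0.57 (edgeR adjusted p = 0.00119 and 0.000858). Of 18 basement membrane and elastic fibre genes 5 fell and 0 rose (0 higher and 7 lower adjusted over the list alone, median log2 fold change -0.69, camera adjusted p = 0.00412, or 0.244 with an estimated correlation). Elastin, ELN, changed by -3.09 ± 0.53, and the vascular collagens COL15A1 by -3.16 ± 0.48 and COL18A1 by -3.05 ± 0.36. TGF-beta and BMP target genes fell in 9 of 18 cases and rose in 1 (1 higher and 13 lower adjusted over the list alone, median log2 fold change -1.46, camera adjusted p = 2.34e-05, or 0.244 with an estimated correlation). The ligand TGFB3 changed by -3.65 ± 0.52, the activin subunit INHBA by -3.31 ± 0.46 and the pathway inhibitor SMAD7 by -2.75 ± 0.32.

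Macrophage markers rose in 7 of 20 cases and fell in 0 (11 higher and 0 lower adjusted over the list alone, median log2 fold change 1.34, camera adjusted p = 2.34e-05, or 0.378 with an estimated correlation). The scavenger receptors CD163 and MSR1 changed by 3.91 ± 0.56 and 2.94 ± 0.36 (edgeR adjusted p = 0.00198 and 0.000982). Schwann cell and neural markers fell in 6 of 12 cases and rose in 0 (0 higher and 7 lower adjusted over the list alone, median log2 fold change -1.66, camera adjusted p = 0.000435, or 0.255 with an estimated correlation). The myelin protein periaxin, PRX, changed by -3.08 ± 0.31. Among adventitial fibroblast markers PI16 (chromosome 7, 32600952 to 32613505) changed by -6.61 ± 0.45 and SFRP4 by -5.52 ± 0.46, while the list of 18 had 3 higher and 3 lower and did not pass the test (camera adjusted p = 0.0670). Cardiomyocyte markers fell in 6 of 9 cases and rose in 0 (0 higher and 7 lower adjusted over the list alone, median log2 fold change -5.81, camera adjusted p = 0.000873, or 0.360 with an estimated correlation), and their median was -5.29 with genes at the count floor set to their bound. These markers differed between the native libraries, with a mean log2 CPM of 6.41 in replicate 1 and 1.76 in replicate 2, and without replicate 1 their median was -1.69, with 1 called. Without stented static replicate 1 the macrophage, oxidative stress and cholesterol synthesis list medians were 0.45, 0.68 and 0.76, and without replicate 2 the contractile one was -5.51. Adipocyte markers had a mean log2 CPM of 7.77 in stented static replicate 1 and 3.29 in replicate 2, against 7.19 and 6.56 in native. Of 5 measured erythrocyte and platelet markers only haemoglobin HBB was called, at 0 counts and at least 581-fold lower, and the list did not pass (camera adjusted p = 0.488).

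Among the genes followed in every comparison, the matricellular protein SPP1 changed by 3.12 ± 0.58 (edgeR adjusted p = 0.00719), a call lost without native replicate 1 (0.0738) or native replicate 2 (0.0697). The cytokine IL6 changed by -3.26 ± 0.75 (adjusted p = 0.0185), and this call was lost without native replicate 1 (0.0610), native replicate 2 (0.103), stented static replicate 1 (0.101) or stented static replicate 2 (0.0679). Endothelial nitric oxide synthase NOS3, the endothelial adhesion protein PECAM1 and collagen COL1A1 did not pass, at 0.43 ± 0.64, -0.26 ± 0.42 and -1.12 ± 0.58. NOS3 was at -1.47 without stented static replicate 1 and 1.22 without replicate 2, and PECAM1, without passing, stood lower still without replicate 1. Without native replicate 1, native replicate 2 or stented static replicate 1 edgeR called 636, 514 and 805 genes instead of 1955, while DESeq2 called 3092 and edgeR called 1232 with the libraries of a single count table. The Y-linked genes EIF1AY and KDM5D had 0 counts in both stented static libraries and 734 and 498 in native, so these groups also differed in Y-linked transcripts.

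**Figure D2:**
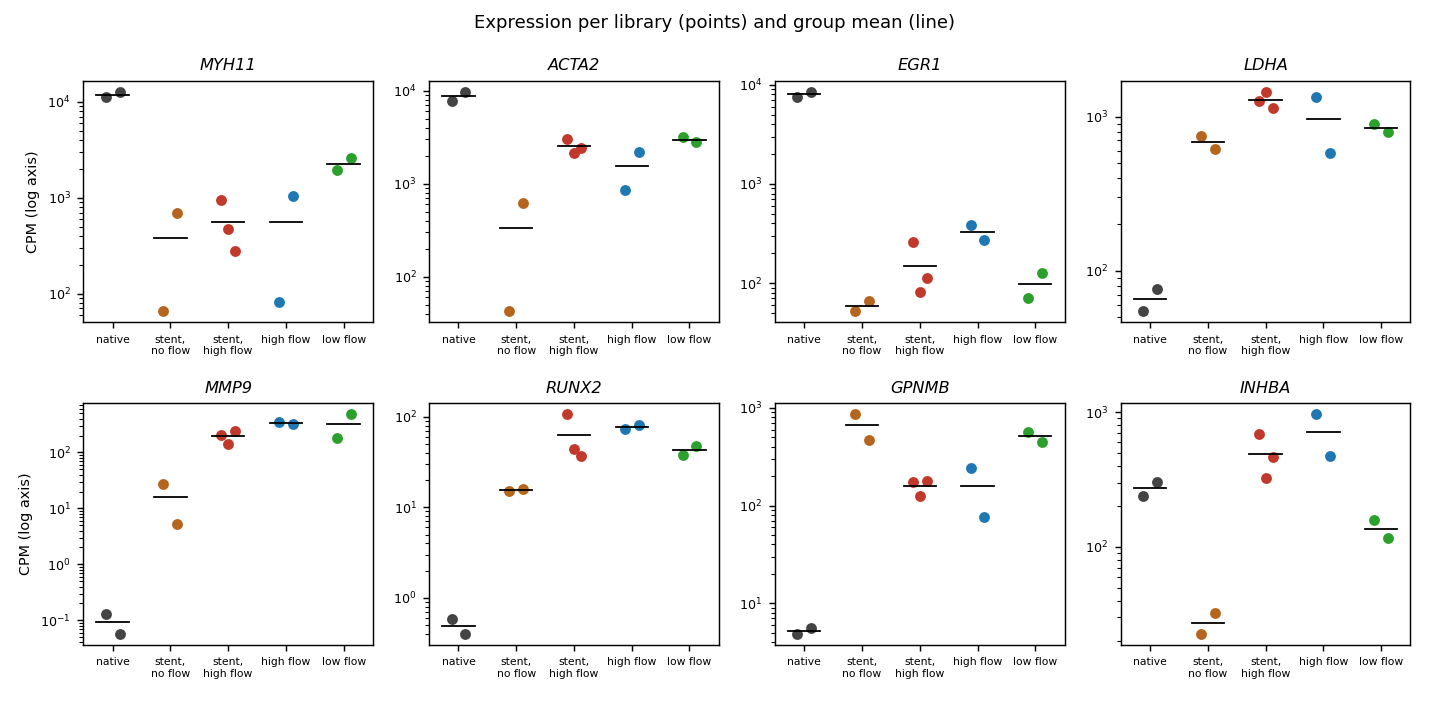
CPM on a log axis for 8 genes, with 1 point per library in 5 groups (native, stented static, stented high-flow, high-flow, low-flow) and the group mean as a line. MYH11, ACTA2 and EGR1 have their highest means in native, LDHA, MMP9 and RUNX2 their lowest, and INHBA is lowest in the stented static group at 27.4 ± 6.68 CPM.

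The second comparison set stented vessels under flow against native arteries. By camera at the preset correlation the lists of matrix proteases, glycolysis and the cell cycle stood higher, and contractile, immediate early, endothelial and Schwann cell lists lower. With an estimated correlation none of the 18 list calls held (adjusted p = 0.143 to 0.533). MMP9 CPM was 2159 (95% counting interval 739 to 10471) times that of native, reaching 195 ± 50.9. Fibronectin, FN1, rose from 1472 ± 32.3 to 27252 ± 13241 CPM, and MYH11 fell from 11875 ± 1044 to 561 ± 337 CPM.

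Proteases and inhibitors of the matrix rose in 13 of 19 cases and fell in 2 (13 higher and 2 lower adjusted over the list alone, median log2 fold change 2.58, camera adjusted p = 1.21e-05, or 0.178 with an estimated correlation). PLAUR changed by 4.65 ± 0.43 and urokinase PLAU by 2.58 ± 0.44 (edgeR adjusted p = 0.000115 and 0.00222). These also belong to the thrombosis and fibrinolysis list, where 6 of 16 rose and 1 fell (6 higher and 1 lower adjusted over the list alone, median log2 fold change 0.91, camera adjusted p = 0.00630, or 0.143 with an estimated correlation). Fibrillar collagen and collagen assembly genes rose in 11 of 22 cases and fell in 1 (12 higher and 1 lower adjusted over the list alone, median log2 fold change 1.26, camera adjusted p = 0.000547, or 0.389 with an estimated correlation). The members with the largest rises were enzymes, the crosslinking oxidase LOXL2 at 3.66 ± 0.51 and the prolyl hydroxylase subunit P4HA3 at 3.29 ± 0.39, while collagen COL1A1 itself did not pass at 0.34 ± 0.53. In the synthetic smooth muscle and matricellular list 6 of 16 rose and 3 fell (8 higher and 3 lower adjusted over the list alone, median log2 fold change 1.03, camera adjusted p = 0.0471, or 0.420 with an estimated correlation). FN1 changed by 4.21 ± 0.70, SPP1 by 4.53 ± 0.60 and S100A4 by 3.80 ± 0.68. That list lost its call without native replicate 1 (camera adjusted p = 0.0705), stented high-flow replicate 1 (0.0656) or stented high-flow replicate 3 (0.0599).

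Cell cycle genes rose in 14 of 26 cases and fell in 0 (16 higher and 0 lower adjusted over the list alone, median log2 fold change 1.67, camera adjusted p = 3.35e-06, or 0.389 with an estimated correlation). Thymidylate synthase TYMS changed by 4.11 ± 0.69 (edgeR adjusted p = 0.00212). Hypoxia and glycolysis genes rose in 14 of 20 cases and fell in 1 (14 higher and 1 lower adjusted over the list alone, median log2 fold change 2.09, camera adjusted p = 1.94e-07, or 0.178 with an estimated correlation). CA12 changed by 4.89 ± 0.34, LDHA by 4.29 ± 0.42 and the angiogenic factor VEGFA by 3.48 ± 0.46, and the lactate exporter SLC16A3 by 7.55 ± 0.83. In the oxidative stress list 11 of 18 rose and 0 fell (13 higher and 0 lower adjusted over the list alone, median log2 fold change 1.15, camera adjusted p = 5.83e-06, or 0.143 with an estimated correlation). Sulfiredoxin SRXN1 changed by 2.34 ± 0.29 and HMOX1 by 3.12 ± 0.42. Of 20 unfolded protein and heat shock genes 11 rose and 1 fell (13 higher and 1 lower adjusted over the list alone, median log2 fold change 1.02, camera adjusted p = 0.000628, or 0.389 with an estimated correlation). Among secreted factors the Wnt antagonist SFRP2 (chromosome 8, 75337311 to 75345926) changed by 8.17 ± 0.98, the glycoprotein CHI3L1 by 8.30 ± 1.28, the protease-like PRSS35 (chromosome 1, 82714880 to 82734883) by 7.58 ± 0.79, the chemokine CXCL14 by 5.80 ± 0.65 and the cytokine LIF by 5.67 ± 0.78 (edgeR adjusted p = 0.000167 to 0.00132). The cytokine and chemokine list had 9 of 22 higher and 5 lower, with 11 higher and 6 lower adjusted over the list alone, and did not pass (camera adjusted p = 0.0525).

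Contractile genes fell in 11 of 17 cases and rose in 0 (1 higher and 15 lower adjusted over the list alone, median log2 fold change -2.09, camera adjusted p = 9.42e-05, or 0.420 with an estimated correlation). MYH11 changed by -4.40 ± 1.04, CNN1 by -3.70 ± 0.82 and leiomodin LMOD1 by -3.81 ± 0.71 (edgeR adjusted p = 0.00362 to 0.0115), whereas ACTA2 at -1.77 ± 0.76 did not pass (adjusted p = 0.114). Immediate early genes fell in 14 of 18 cases and rose in 1 (1 higher and 14 lower adjusted over the list alone, median log2 fold change -3.30, camera adjusted p = 1.69e-09, or 0.143 with an estimated correlation). FOSB changed by -7.46 ± 0.82, FOS by -6.57 ± 0.73 and NR4A1 by -5.90 ± 0.46. Endothelial identity genes fell in 10 of 17 cases and rose in 1 (1 higher and 11 lower adjusted over the list alone, median log2 fold change -1.37, camera adjusted p = 0.000833, or 0.420 with an estimated correlation). The angiopoietin receptor TEK changed by -3.21 ± 0.50, the VEGF receptor KDR by -2.75 ± 0.51 and PECAM1 by -1.71 ± 0.38 (edgeR adjusted p = 0.00144 to 0.00904), and PECAM1 lost its call without native replicate 2 (0.0760). In the flow-responsive endothelial list 2 of 16 rose and 7 fell, with 2 higher and 7 lower adjusted over the list alone, without passing as a list (camera adjusted p = 0.0587). KLF4 and KLF2 changed by -2.92 ± 0.31 and -2.12 ± 0.44, argininosuccinate synthase ASS1 changed by -4.93 ± 0.85, and NOS3 did not pass at -1.03 ± 0.58. IL6 did not pass at -0.22 ± 0.61, but was called at -1.32 without stented high-flow replicate 3 (adjusted p = 0.0463).

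Markers of several other cell types were lower. Schwann cell and neural markers fell in 10 of 12 cases and rose in 0 (0 higher and 11 lower adjusted over the list alone, median log2 fold change -3.30, camera adjusted p = 4.37e-07, or 0.143 with an estimated correlation). The sodium channel SCN7A changed by -5.08 ± 0.69 (edgeR adjusted p = 0.000715). Adipocyte markers fell in 10 of 15 cases and rose in 0 (0 higher and 12 lower adjusted over the list alone, median log2 fold change -4.09, camera adjusted p = 2.70e-05, or 0.389 with an estimated correlation). The lipid droplet protein PLIN4 changed by -5.72 ± 1.26. Cardiomyocyte markers fell in 7 of 9 cases and rose in 0 (0 higher and 7 lower adjusted over the list alone, median log2 fold change -6.52, camera adjusted p = 0.000490, or 0.371 with an estimated correlation). Their median without native replicate 1 was -2.41, with 2 called. Lymphocyte markers fell in 6 of 10 cases and rose in 0 (0 higher and 6 lower adjusted over the list alone, median log2 fold change -4.70, camera adjusted p = 0.00441, or 0.371 with an estimated correlation), and their median was -4.80 with genes at the count floor set to their bound. Adventitial fibroblast markers fell in 9 of 18 cases and rose in 4 (4 higher and 11 lower adjusted over the list alone, median log2 fold change -1.79, camera adjusted p = 0.0222, or 0.178 with an estimated correlation). PI16 changed by -6.22 ± 0.37 against SFRP2, which rose. Macrophage markers had 4 of 20 higher and 1 lower and did not pass as a list (camera adjusted p = 0.232). The neurotrophin receptor NTRK2 (chromosome 10, 30030050 to 30429938) changed by -5.78 ± 0.40 and the matrix protease ADAMTS15 by -6.91 ± 0.67.

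Elastin changed by -3.34 ± 0.46 (edgeR adjusted p = 0.000720), and the basement membrane and elastic fibre list had 3 of 18 higher and 6 lower without passing (camera adjusted p = 0.0901). Mitochondrially encoded genes fell in 10 of 13 cases and rose in 0 (0 higher and 10 lower adjusted over the list alone, median log2 fold change -1.85, camera adjusted p = 3.35e-06, or 0.371 with an estimated correlation). CYTB changed by -3.61 ± 0.36. Interferon response genes fell in 4 of 23 cases and rose in 0 (0 higher and 3 lower adjusted over the list alone, median log2 fold change -0.69, camera adjusted p = 0.0318, or 0.533 with an estimated correlation). The GTPase GBP1 changed by -3.01 ± 0.30, and the list lost its call without stented high-flow replicate 3 (camera adjusted p = 0.137). Osteochondrogenic genes had 5 of 15 higher and 3 lower with no call as a list (camera adjusted p = 0.593), and RUNX2 rose by 6.97 ± 0.59. Fatty acid oxidation genes had 1 of 20 higher and 5 lower, also without a call as a list (camera adjusted p = 0.159). Without native replicate 1, native replicate 2 or stented high-flow replicate 2 edgeR called 1542, 1691 and 2464 genes instead of 3737.

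**Figure D3:**
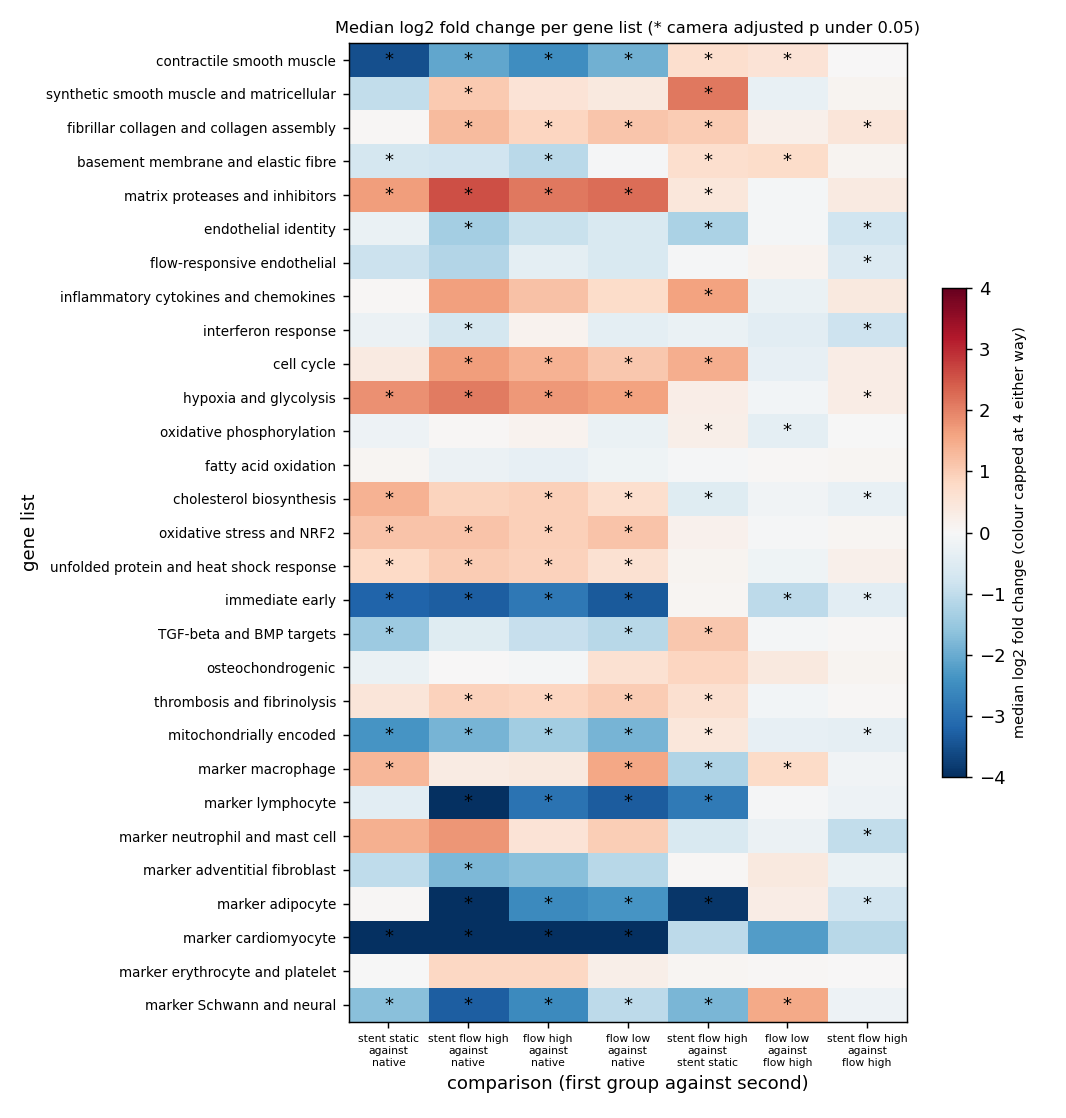
Median log2 fold change of 29 gene lists (vertical axis) in 7 comparisons (horizontal axis), with red for higher and blue for lower in the first group and a star where the camera adjusted p was under 0.05. Immediate early genes are blue and starred in all 4 comparisons with native, with medians from -3.36 to -2.85, and hypoxia and glycolysis genes are red and starred, with medians from 1.60 to 2.09.

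The third comparison set vessels without a stent under high flow against native arteries. As in the stented vessels, the matrix protease and glycolysis lists stood higher and the contractile and immediate early lists lower by camera, and none of the 16 list calls held with an estimated correlation (adjusted p = 0.130 to 0.571). MMP9 CPM was 3644 (95% counting interval 1246 to 17670.1) times that of native. The protease inhibitor TIMP1 (chromosome X, 42103251 to 42106289) rose from 134 ± 16.3 to 3861 ± 510.0 CPM, RUNX2 from 0.494 ± 0.130 to 77.6 ± 5.72 CPM, and EGR1 fell from 8035 ± 599 to 330.0 ± 80.9 CPM.

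Of 19 matrix protease and inhibitor genes 9 rose and 2 fell (13 higher and 2 lower adjusted over the list alone, median log2 fold change 2.12, camera adjusted p = 1.52e-05, or 0.206 with an estimated correlation). TIMP1 changed by 4.85 ± 0.45 (edgeR adjusted p = 0.000350). The thrombosis and fibrinolysis list had 6 of 16 higher and 1 lower (8 higher and 1 lower adjusted over the list alone, median log2 fold change 0.86, camera adjusted p = 0.00260, or 0.130 with an estimated correlation). PLAUR changed by 4.26 ± 0.43. Of 22 fibrillar collagen and assembly genes 7 rose and 1 fell (8 higher and 1 lower adjusted over the list alone, median log2 fold change 0.87, camera adjusted p = 0.0154, or 0.526 with an estimated correlation). P4HA3 changed by 3.24 ± 0.40, and this list lost its call without high-flow replicate 1 (camera adjusted p = 0.205). Of 18 basement membrane and elastic fibre genes 5 fell and 2 rose (2 higher and 8 lower adjusted over the list alone, median log2 fold change -1.07, camera adjusted p = 0.0289, or 0.339 with an estimated correlation). ELN changed by -3.46 ± 0.54 and COL18A1 by -2.01 ± 0.35. That call was lost without native replicate 1 (0.0634) or high-flow replicate 2 (0.0575). SPP1 changed by 4.35 ± 0.61, RUNX2 by 7.29 ± 0.61, SFRP2 by 8.66 ± 1.01, PRSS35 by 7.40 ± 0.80 and CXCL14 by 6.03 ± 0.67 (edgeR adjusted p = 0.000236 to 0.00174).

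Hypoxia and glycolysis genes rose in 13 of 20 cases and fell in 1 (15 higher and 2 lower adjusted over the list alone, median log2 fold change 1.73, camera adjusted p = 2.26e-07, or 0.206 with an estimated correlation). CA12 changed by 4.37 ± 0.34, LDHA by 3.87 ± 0.43 and VEGFA by 3.00 ± 0.46 (edgeR adjusted p = 0.000236 to 0.00252). Oxidative stress genes rose in 9 of 18 cases and fell in 0 (11 higher and 0 lower adjusted over the list alone, median log2 fold change 0.96, camera adjusted p = 6.84e-06, or 0.130 with an estimated correlation). HMOX1 changed by 2.88 ± 0.44 and peroxiredoxin PRDX1 by 2.11 ± 0.27. Cell cycle genes rose in 4 of 26 cases and fell in 0 (9 higher and 0 lower adjusted over the list alone, median log2 fold change 1.39, camera adjusted p = 1.52e-05, or 0.478 with an estimated correlation). Of 20 unfolded protein and heat shock genes 6 rose and 1 fell (12 higher and 2 lower adjusted over the list alone, median log2 fold change 0.91, camera adjusted p = 0.00383, or 0.485 with an estimated correlation). Of 23 cholesterol synthesis genes 6 rose and 1 fell (9 higher and 2 lower adjusted over the list alone, median log2 fold change 0.96, camera adjusted p = 0.00484, or 0.571 with an estimated correlation). This list call was lost without high-flow replicate 1 (camera adjusted p = 0.127). Mitochondrially encoded genes fell in 6 of 13 cases and rose in 0 (0 higher and 10 lower adjusted over the list alone, median log2 fold change -1.40, camera adjusted p = 4.39e-05, or 0.454 with an estimated correlation).

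Contractile genes fell in 10 of 17 cases and rose in 0 (1 higher and 12 lower adjusted over the list alone, median log2 fold change -2.50, camera adjusted p = 1.52e-05, or 0.456 with an estimated correlation). CNN1 changed by -4.24 ± 0.99 (edgeR adjusted p = 0.0173), a call lost without native replicate 1 (0.0509), native replicate 2 (0.0711) or high-flow replicate 1 (0.0894). MYH11 changed by -4.42 ± 1.23 (adjusted p = 0.0343), a call lost without the same libraries (0.0930, 0.103 and 0.140), and its log2 fold change was -7.13 without high-flow replicate 2. ACTA2 did not pass at -2.50 ± 0.89 (adjusted p = 0.0828). The calcium-binding troponin TNNC1 changed by -6.11 ± 1.08 and the matrix glycoprotein TNXB by -5.89 ± 0.62. Immediate early genes fell in 12 of 18 cases and rose in 0 (1 higher and 14 lower adjusted over the list alone, median log2 fold change -2.85, camera adjusted p = 1.28e-08, or 0.130 with an estimated correlation). NR4A3 changed by -4.81 ± 0.53 and EGR1 by -4.61 ± 0.58. KLF4 changed by -3.52 ± 0.37 (adjusted p = 0.000581). KLF2 changed by -1.97 ± 0.51 (adjusted p = 0.0249), a call lost without native replicate 1 (0.0920), native replicate 2 (0.106), high-flow replicate 1 (0.166) or high-flow replicate 2 (0.0819). NOS3, PECAM1, COL1A1 and IL6 did not pass, at -0.08 ± 0.64, -0.89 ± 0.43, -0.05 ± 0.57 and 0.00 ± 0.67.

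Schwann cell and neural markers fell in 9 of 12 cases and rose in 0 (0 higher and 12 lower adjusted over the list alone, median log2 fold change -2.56, camera adjusted p = 2.26e-07, or 0.130 with an estimated correlation). Myelin basic protein MBP changed by -3.99 ± 0.50, and NTRK2 changed by -5.13 ± 0.47 (edgeR adjusted p = 0.000347). Adipocyte markers fell in 4 of 15 cases and rose in 0 (0 higher and 8 lower adjusted over the list alone, median log2 fold change -2.56, camera adjusted p = 0.000246, or 0.478 with an estimated correlation), with list means of 2.43 and 4.36 log2 CPM in the high-flow libraries. Cardiomyocyte markers fell in 6 of 9 cases and rose in 0 (0 higher and 6 lower adjusted over the list alone, median log2 fold change -6.35, camera adjusted p = 0.00299, or 0.454 with an estimated correlation). Their median without native replicate 1 was -1.26, with 1 called. Lymphocyte markers fell in 4 of 10 and rose in 0 (0 higher and 6 lower adjusted over the list alone, median log2 fold change -2.94, camera adjusted p = 0.00732, or 0.436 with an estimated correlation). The fibroblast marker PI16 changed by -5.35 ± 0.42. Without native replicate 1, native replicate 2, high-flow replicate 1 or high-flow replicate 2 edgeR called 752, 808, 772 and 1318 genes instead of 2272.

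The fourth comparison set vessels without a stent under low flow against native arteries. By camera at the preset correlation the lists of macrophage markers, matrix proteases and glycolysis stood higher and the immediate early list lower. None of the 17 list calls held with an estimated correlation (adjusted p = 0.128 to 0.597). Fewer contractile genes passed the test than against the other cultures, a difference not tested in itself. GPNMB rose from 5.26 ± 0.533 to 511 ± 83.8 CPM and MMP9 CPM was 3759 (95% counting interval 1286 to 18231) times that of native. MYH11 was at 2256 ± 441 CPM against 11875 ± 1044 CPM in native and did not pass the test.

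Macrophage markers rose in 5 of 20 cases and fell in 0 (10 higher and 0 lower adjusted over the list alone, median log2 fold change 1.55, camera adjusted p = 0.000183, or 0.502 with an estimated correlation). GPNMB changed by 6.60 ± 0.61 and MSR1 by 3.22 ± 0.36 (edgeR adjusted p = 0.000261 and 0.000705). Matrix protease and inhibitor genes rose in 10 of 19 cases and fell in 1 (11 higher and 1 lower adjusted over the list alone, median log2 fold change 2.23, camera adjusted p = 3.78e-05, or 0.266 with an estimated correlation). TIMP1 changed by 3.17 ± 0.41. The thrombosis and fibrinolysis list had 4 of 16 higher and 1 lower (5 higher and 1 lower adjusted over the list alone, median log2 fold change 1.02, camera adjusted p = 0.00436, or 0.219 with an estimated correlation). Fibrillar collagen and assembly genes rose in 7 of 22 cases and fell in 0 (10 higher and 1 lower adjusted over the list alone, median log2 fold change 1.10, camera adjusted p = 0.000573, or 0.488 with an estimated correlation). RUNX2 changed by 6.43 ± 0.59, SPP1 by 4.61 ± 0.62, SFRP2 by 7.22 ± 0.96 and CHI3L1 by 8.37 ± 1.30 (edgeR adjusted p = 0.000261 to 0.00317). TNXB changed by -5.01 ± 0.59 and PI16 by -4.86 ± 0.41.

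Hypoxia and glycolysis genes rose in 12 of 20 cases and fell in 0 (13 higher and 1 lower adjusted over the list alone, median log2 fold change 1.60, camera adjusted p = 5.23e-07, or 0.266 with an estimated correlation). CA12 changed by 5.04 ± 0.35, LDHA by 3.69 ± 0.42 and HK2 by 3.06 ± 0.49 (edgeR adjusted p = 0.000122 to 0.00369). Oxidative stress genes rose in 10 of 18 cases and fell in 0 (11 higher and 0 lower adjusted over the list alone, median log2 fold change 1.14, camera adjusted p = 2.69e-05, or 0.219 with an estimated correlation). HMOX1 changed by 3.17 ± 0.44. Of 26 cell cycle genes 1 rose and 0 fell (1 higher and 0 lower adjusted over the list alone, median log2 fold change 1.07, camera adjusted p = 0.000621, or 0.541 with an estimated correlation). Of 23 cholesterol synthesis genes 1 rose and 1 fell (5 higher and 2 lower adjusted over the list alone, median log2 fold change 0.66, camera adjusted p = 0.0373, or 0.597 with an estimated correlation). This list call was lost without native replicate 1 (camera adjusted p = 0.0825) or low-flow replicate 1 (0.201). Of 20 unfolded protein and heat shock genes 5 rose and 1 fell (6 higher and 1 lower adjusted over the list alone, median log2 fold change 0.62, camera adjusted p = 0.0289, or 0.561 with an estimated correlation). This list call was lost without the same libraries (0.0758 and 0.108). Mitochondrially encoded genes fell in 9 of 13 cases and rose in 0 (0 higher and 10 lower adjusted over the list alone, median log2 fold change -1.85, camera adjusted p = 7.22e-07, or 0.426 with an estimated correlation). CYTB changed by -3.32 ± 0.42.

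Immediate early genes fell in 14 of 18 cases and rose in 0 (0 higher and 16 lower adjusted over the list alone, median log2 fold change -3.36, camera adjusted p = 5.60e-14, or 0.128 with an estimated correlation). FOSB changed by -9.02 ± 1.06, FOS by -7.38 ± 0.91, NR4A1 by -6.63 ± 0.57 and EGR1 by -6.36 ± 0.63 (edgeR adjusted p = 0.000247 to 0.000966). TGF-beta and BMP target genes fell in 8 of 18 cases and rose in 1 (1 higher and 8 lower adjusted over the list alone, median log2 fold change -1.11, camera adjusted p = 0.00903, or 0.469 with an estimated correlation). The BMP-induced ID2 changed by -2.93 ± 0.31 and SMAD7 by -2.25 ± 0.31, and the list lost its call without native replicate 2 (camera adjusted p = 0.0841) or low-flow replicate 1 (0.0572). Contractile genes fell in 4 of 17 cases and rose in 0 (0 higher and 8 lower adjusted over the list alone, median log2 fold change -1.92, camera adjusted p = 0.000523, or 0.502 with an estimated correlation). LMOD1 changed by -2.75 ± 0.79 and smoothelin SMTN by -1.62 ± 0.39 (edgeR adjusted p = 0.0451 and 0.0236). Both calls were lost without native replicate 1 (0.114 and 0.102), native replicate 2 (0.160 and 0.0948), low-flow replicate 1 (0.245 and 0.183) or low-flow replicate 2 (0.181 and 0.110). MYH11, ACTA2 and CNN1 did not pass, at -2.40 ± 1.12, -1.54 ± 0.86 and -2.92 ± 0.93 (adjusted p = 0.187, 0.269 and 0.0648).

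KLF4 changed by -2.89 ± 0.35 (edgeR adjusted p = 0.000966). KLF2 changed by -2.50 ± 0.52 and IL6 by -3.39 ± 0.75 (adjusted p = 0.0118 and 0.0156), and both calls were lost without native replicate 1 (0.0530 and 0.0566), native replicate 2 (0.0611 and 0.0830), low-flow replicate 1 (0.124 and 0.101) or low-flow replicate 2 (0.0610 and 0.134). NOS3, PECAM1 and COL1A1 did not pass, at 0.55 ± 0.64, -0.56 ± 0.42 and 0.11 ± 0.57. Schwann cell and neural markers fell in 5 of 12 cases and rose in 0 (0 higher and 6 lower adjusted over the list alone, median log2 fold change -1.03, camera adjusted p = 0.000335, or 0.266 with an estimated correlation). Adipocyte markers fell in 3 of 15 cases and rose in 0 (0 higher and 3 lower adjusted over the list alone, median log2 fold change -2.36, camera adjusted p = 0.00108, or 0.502 with an estimated correlation). Cardiomyocyte markers fell in 6 of 9 and rose in 0 (0 higher and 8 lower adjusted over the list alone, median log2 fold change -6.58, camera adjusted p = 0.000196, or 0.426 with an estimated correlation). Their median without native replicate 1 was -3.47, with 2 called. Lymphocyte markers fell in 4 of 10 and rose in 0 (2 higher and 6 lower adjusted over the list alone, median log2 fold change -3.33, camera adjusted p = 0.00536, or 0.449 with an estimated correlation). Without native replicate 1, native replicate 2, low-flow replicate 1 or low-flow replicate 2 edgeR called 514, 556, 361 and 405 genes instead of 1904, and DESeq2 on all libraries called 2902. KDM5D had 0 counts and EIF1AY 1 count over the low-flow libraries, against 498 and 734 in native.

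**Figure D4:**
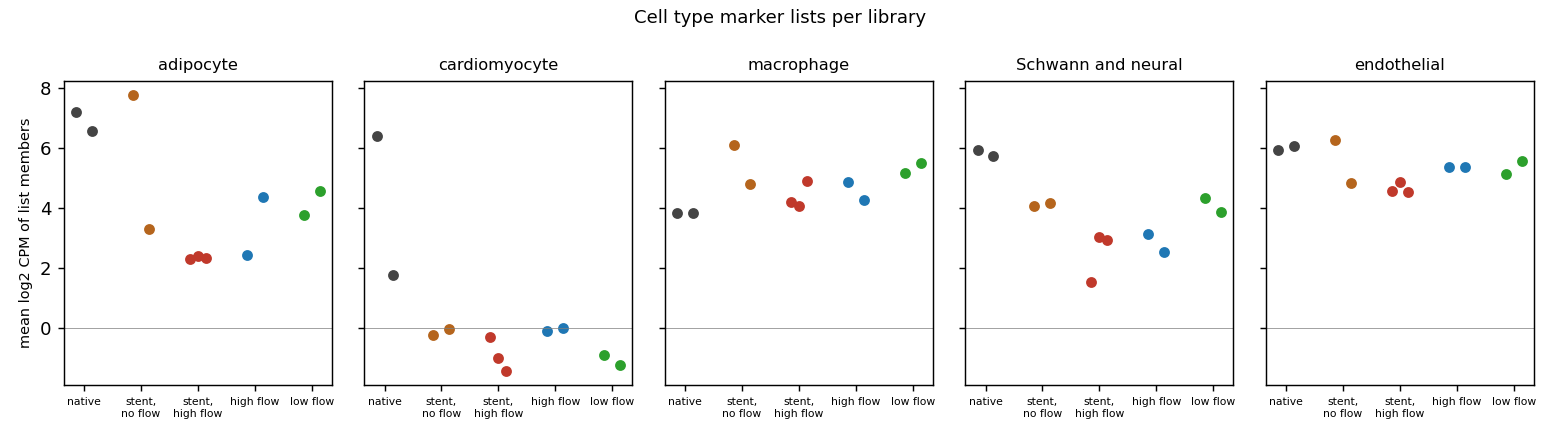
Mean log2 CPM of the members of 5 marker lists (panels), with 1 point per library in the 5 groups. Adipocyte markers reach 7.77 in stented static replicate 1 and lie at 2.29 to 4.54 in the other cultured libraries, and cardiomyocyte markers stand at 6.41 in native replicate 1 and 1.76 in native replicate 2.

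The fifth comparison set stented vessels under flow against stented vessels held static. Under flow, the activin subunit INHBA, the serine protease CORIN, the adipokine-like C1QTNF3 and PRSS35 were higher, and NTRK2, the metallothionein MT1X and the lipase LPL were lower. None of the 17 list calls held with an estimated correlation (adjusted p = 0.224 to 0.634). INHBA was at 492 ± 184 CPM under flow and 27.4 ± 6.68 CPM in static vessels, and NTRK2 at 3.67 ± 1.08 and 103 ± 55.8 CPM. In all, edgeR called 438 genes, 181 higher and 257 lower, against 1368 by DESeq2, 1003 without a filter, 32 with only the groups compared and 160 with the libraries of a single count table.

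Synthetic smooth muscle and matricellular genes rose in 5 of 16 cases and fell in 0 (10 higher and 0 lower adjusted over the list alone, median log2 fold change 2.11, camera adjusted p = 1.99e-08, or 0.224 with an estimated correlation). The growth factor-like CCN2 changed by 2.96 ± 0.41 (edgeR adjusted p = 0.00704). Cytokine and chemokine genes rose in 7 of 22 cases and fell in 0 (12 higher and 1 lower adjusted over the list alone, median log2 fold change 1.61, camera adjusted p = 2.49e-05, or 0.368 with an estimated correlation). LIF changed by 4.44 ± 0.72, IL1A by 4.71 ± 0.78, the prostaglandin synthase PTGS2 by 3.98 ± 0.65 and IL6 by 3.04 ± 0.71 (adjusted p = 0.0125, 0.0134, 0.0134 and 0.0484). TGF-beta and BMP targets rose in 4 of 18 cases and fell in 0 (7 higher and 0 lower adjusted over the list alone, median log2 fold change 1.08, camera adjusted p = 9.74e-05, or 0.361 with an estimated correlation). INHBA changed by 4.17 ± 0.47 (adjusted p = 0.00290). Fibrillar collagen and assembly genes rose in 2 of 22 cases and fell in 0 (11 higher and 1 lower adjusted over the list alone, median log2 fold change 1.01, camera adjusted p = 7.03e-06, or 0.368 with an estimated correlation). Cell cycle genes were called in 0 of 26 cases over all genes (10 higher and 0 lower adjusted over the list alone, median log2 fold change 1.47, camera adjusted p = 1.99e-08, or 0.368 with an estimated correlation). Matrix protease and inhibitor genes rose in 3 of 19 cases and fell in 0 (7 higher and 0 lower adjusted over the list alone, median log2 fold change 0.45, camera adjusted p = 0.00189, or 0.368 with an estimated correlation). MMP9 changed by 3.59 ± 0.67 and TIMP1 by 2.21 ± 0.38, and this list lost its call without stented static replicate 2 (camera adjusted p = 0.0781). PRSS35 changed by 7.36 ± 0.77, C1QTNF3 by 6.40 ± 0.82, CORIN by 4.97 ± 0.53 and SFRP2 by 4.92 ± 0.82 (edgeR adjusted p = 0.00243, 0.00529, 0.00249 and 0.0147).

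Contractile genes had 1 of 17 higher and 0 lower (3 higher and 0 lower adjusted over the list alone, median log2 fold change 0.68, camera adjusted p = 0.00157, or 0.550 with an estimated correlation). That member, ACTG2, changed by 4.21 ± 0.84 (edgeR adjusted p = 0.0280), and by a log2 value of 6.50 without stented static replicate 2. The list lost its call without stented static replicate 1 (camera adjusted p = 0.229) or stented high-flow replicate 1 (0.0647). MYH11, ACTA2 and CNN1 did not pass, at 0.58 ± 0.99, 2.93 ± 0.87 and 1.40 ± 0.83, nor did KLF2, KLF4, NOS3, PECAM1, COL1A1 and SPP1, at 0.21 ± 0.45, 0.13 ± 0.30, -1.46 ± 0.58, -1.45 ± 0.38, 1.46 ± 0.55 and 1.40 ± 0.51. Thrombosis and fibrinolysis genes had 2 of 16 higher and 0 lower (6 higher and 0 lower adjusted over the list alone, median log2 fold change 0.64, camera adjusted p = 0.00289, or 0.224 with an estimated correlation). This list call was lost without stented static replicate 2 (0.315). Endothelial identity genes had 0 of 17 called over all genes (1 higher and 10 lower adjusted over the list alone, median log2 fold change -1.27, camera adjusted p = 0.000402, or 0.492 with an estimated correlation). This list call was lost without stented static replicate 1 (0.488). At the preset correlation basement membrane, oxidative phosphorylation and mitochondrially encoded genes stood higher and cholesterol synthesis genes lower (camera adjusted p = 0.0417, 0.00829, 0.0153 and 0.0112). With an estimated correlation the adjusted p was 0.368, 0.550, 0.588 and 0.634, and each list lost its call in at least 2 of the fits with 1 library left out.

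Adipocyte markers fell in 7 of 15 cases and rose in 0 (0 higher and 14 lower adjusted over the list alone, median log2 fold change -3.90, camera adjusted p = 1.36e-06, or 0.368 with an estimated correlation). LPL changed by -3.99 ± 0.72 (edgeR adjusted p = 0.0187). Macrophage markers fell in 2 of 20 cases and rose in 0 (0 higher and 13 lower adjusted over the list alone, median log2 fold change -1.20, camera adjusted p = 4.38e-06, or 0.368 with an estimated correlation). This list call was lost without stented static replicate 1 (camera adjusted p = 0.0572). Schwann cell and neural markers fell in 2 of 12 cases and rose in 0 (0 higher and 7 lower adjusted over the list alone, median log2 fold change -1.81, camera adjusted p = 3.38e-05, or 0.338 with an estimated correlation). Lymphocyte markers fell in 1 of 10 and rose in 0 (0 higher and 6 lower adjusted over the list alone, median log2 fold change -2.82, camera adjusted p = 0.000169, or 0.361 with an estimated correlation), and their median was -2.51 with genes at the count floor set to their bound. NTRK2 changed by -4.81 ± 0.39, MT1X by -5.42 ± 0.78, the sorting receptor SORL1 by -3.24 ± 0.45, the prothrombinase-like FGL2 by -3.12 ± 0.43, angiotensinogen AGT by -3.06 ± 0.46 and the lipid phosphatase PLPP3 by -1.56 ± 0.24 (edgeR adjusted p = 0.000518, 0.00819, 0.00704, 0.00704, 0.00937 and 0.0112). Stented static replicate 1 stood above replicate 2 in adipocyte markers, at a mean log2 CPM of 7.77 against 3.29, and in MT1X, at 2247 against 291 CPM.

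The size of this comparison depended on single libraries. Without stented static replicate 1 the list medians of contractile, endothelial identity, macrophage and adipocyte genes were -0.03, -0.29, -0.57 and -1.39. Without stented static replicate 1 edgeR called 95 genes, of which 76 were among the 438. Without stented static replicate 2 it called 784, of which 340 were, and without stented high-flow replicate 2 it called 175, of which 159 were. Of the named genes PRSS35, CORIN, C1QTNF3, INHBA, MMP9, TIMP1, MT1X, NTRK2, SORL1, FGL2 and PLPP3 kept their calls whichever library was left out, with MT1X at -3.30 without stented static replicate 1. Without that library the log2 fold change (edgeR adjusted p) was 4.23 (0.0803) for SFRP2, 4.70 (0.0810) for LIF, 5.13 (0.0917) for IL1A, 2.57 (0.0516) for CCN2, 3.93 (0.0979) for PTGS2, 3.36 (0.0573) for ACTG2, -2.09 (0.0524) for AGT and -2.62 (0.125) for LPL. IL6 lost its call without stented static replicate 1 (0.265, at a log2 value of 3.07), stented static replicate 2 (0.117) or stented high-flow replicate 2 (0.0668), and it changed by 1.94 without stented high-flow replicate 3. EIF1AY and KDM5D had 0 counts in both static libraries and 929 and 691 under flow. Leaving out only Y-linked genes, chosen after seeing the data, gave 435 calls, which cannot test sex.

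The sixth comparison set low flow against high flow in vessels without a stent. It called 16 genes, 4 higher and 12 lower under low flow, against 1236 at an unadjusted p under 0.05, and DESeq2 called 105. The creatine synthesis enzyme GATM (chromosome 1, 126361968 to 126378705) was at 45.2 ± 4.85 CPM under low flow and 9.19 ± 4.21 CPM under high flow, and the tight junction protein paracingulin, CGNL1 (chromosome 1, 114424148 to 114628331), at 178 ± 6.65 and 62.4 ± 4.31 CPM. The log2 fold changes were 2.30 ± 0.36 and 1.52 ± 0.24 (edgeR adjusted p = 0.0497 for both). The vasopressin receptor AVPR1A, chosen after its values were seen, changed by -4.44 ± 0.57 (adjusted p = 0.0113). The other 13 genes set the low-flow and stented static libraries together, more than 2 log2 units away from all the rest, 11 lower and 2 higher, and among them were the Y-linked KDM5D and EIF1AY.

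GATM lost its call without high-flow replicate 1 (edgeR adjusted p = 0.0541), high-flow replicate 2 (0.254), low-flow replicate 1 (0.208) or low-flow replicate 2 (0.420). CGNL1 lost its call without the same libraries (0.277, 0.342, 0.347 and 0.562). The number of genes called was 10 without low-flow replicate 1 and 5 without low-flow replicate 2. Without mitochondrially encoded genes 14 genes were called, 2 of them higher, instead of 4 of 16.

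No fixed list had a member called over all genes. Basement membrane and elastic fibre genes stood higher under low flow (1 higher and 0 lower adjusted over the list alone, median log2 fold change 0.72, camera adjusted p = 0.000138, or 0.239 with an estimated correlation). Macrophage markers stood higher too (0 higher and 0 lower adjusted over the list alone, median log2 fold change 0.76, camera adjusted p = 0.000157, or 0.795 with an estimated correlation). Schwann cell and neural markers did likewise (0 higher and 0 lower adjusted over the list alone, median log2 fold change 1.52, camera adjusted p = 0.000125, or 0.367 with an estimated correlation). Immediate early genes stood lower (0 higher and 6 lower adjusted over the list alone, median log2 fold change -1.06, camera adjusted p = 9.80e-08, or 0.239 with an estimated correlation). Nuclear oxidative phosphorylation genes also stood lower (0 higher and 0 lower adjusted over the list alone, median log2 fold change -0.40, camera adjusted p = 1.22e-05, or 0.616 with an estimated correlation). Contractile genes stood higher (0 higher and 0 lower adjusted over the list alone, median log2 fold change 0.56, camera adjusted p = 0.0476, or 0.795 with an estimated correlation). This ended without high-flow replicate 1, where the direction turned (camera adjusted p = 0.919), or without low-flow replicate 2 (0.0763). Of the genes followed throughout, MYH11, ACTA2, CNN1, KLF2, KLF4, NOS3, PECAM1, COL1A1, SPP1 and IL6 did not pass edgeR's test, at 2.02 ± 1.11, 0.96 ± 0.85, 1.32 ± 0.88, -0.53 ± 0.49, 0.63 ± 0.33, 0.63 ± 0.64, 0.33 ± 0.42, 0.16 ± 0.57, 0.26 ± 0.53 and -3.39 ± 0.75.

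The last comparison set stented against unstented vessels under high flow. edgeR called 0 genes, against 467 at an unadjusted p under 0.05, while DESeq2 called 6 and limma-voom 0, and without stented high-flow replicate 1 edgeR called 1. Log2 fold changes were 0.01 ± 0.97 for MYH11, 0.72 ± 0.78 for ACTA2, 0.54 ± 0.81 for CNN1, -0.14 ± 0.44 for KLF2, 0.60 ± 0.31 for KLF4, -0.95 ± 0.58 for NOS3, -0.82 ± 0.38 for PECAM1, 0.39 ± 0.53 for COL1A1, 0.18 ± 0.49 for SPP1 and -0.22 ± 0.61 for IL6. Simulated changes of 4-fold were recovered in 60.4% of cases in this comparison and changes of 2-fold in 6.48%, so smaller differences were mostly not detectable at this size.

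No list had a member called over all genes. Endothelial identity genes stood lower in the stented vessels (0 higher and 0 lower adjusted over the list alone, median log2 fold change -0.81, camera adjusted p = 9.60e-06, or 0.625 with an estimated correlation). At the preset correlation this list call held whichever library was left out, but it was lost with fry. Flow-responsive endothelial genes (0 higher and 0 lower adjusted over the list alone, median log2 fold change -0.56, camera adjusted p = 0.0187, or 0.397 with an estimated correlation) stood lower too, a call lost without stented high-flow replicate 3 (camera adjusted p = 0.162) or high-flow replicate 1 (0.141). Interferon response genes stood lower (0 higher and 0 lower adjusted over the list alone, median log2 fold change -0.83, camera adjusted p = 2.87e-05, or 0.625 with an estimated correlation), and without high-flow replicate 1 the direction turned (0.971). Immediate early genes stood lower (0 higher and 4 lower adjusted over the list alone, median log2 fold change -0.43, camera adjusted p = 2.87e-05, or 0.397 with an estimated correlation), a call that ended without high-flow replicate 1 (0.0524). Fibrillar collagen and assembly genes stood higher (0 higher and 0 lower adjusted over the list alone, median log2 fold change 0.49, camera adjusted p = 0.000139, or 0.626 with an estimated correlation), a call that ended without high-flow replicate 2 (0.792). Neutrophil and mast cell markers stood lower (0 higher and 0 lower adjusted over the list alone, median log2 fold change -0.97, camera adjusted p = 0.0372, or 0.397 with an estimated correlation), a call that ended without stented high-flow replicate 1 (0.131), stented high-flow replicate 2 (0.103), high-flow replicate 1 (0.207) or high-flow replicate 2 (0.136). At the preset correlation hypoxia and glycolysis genes stood higher and cholesterol synthesis genes, mitochondrially encoded genes and adipocyte markers lower (camera adjusted p = 0.0321, 0.0321, 0.00156 and 0.0372). With an estimated correlation the adjusted p was 0.794, 0.844, 0.794 and 0.844, and each list lost its call in at least 2 of the fits with 1 library left out. The direction turned without high-flow replicate 2 for hypoxia and glycolysis (0.792) and without high-flow replicate 1 for cholesterol synthesis (0.323).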

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

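Tests of causes here were chosen after the comparisons were seen. Their intervals are over genes and leave out library spread. The bounds for sex, adipose tissue and a change of scaling were written before the tested values were seen, and those for the other tests after.

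Cultured groups differed by edgeR's test of the difference itself in these cases. Between stented high-flow and stented static vessels 438 genes differed, with log2 differences of PRSS35 7.36, CORIN 4.97, C1QTNF3 6.40, SFRP2 4.92, LIF 4.44, ACTG2 4.21, INHBA 4.17, IL1A 4.71, CCN2 2.96, TIMP1 2.21, MMP9 3.59, PTGS2 3.98 and IL6 3.04, and of MT1X -5.42, NTRK2 -4.81, LPL -3.99, SORL1 -3.24, FGL2 -3.12, AGT -3.06 and PLPP3 -1.56. Between low-flow and high-flow vessels 16 genes differed, among them GATM 2.30, CGNL1 1.52, AVPR1A -4.44, KDM5D -11.70 and EIF1AY -9.32. KDM5D had 0 counts under low flow, at least 361-fold below high flow, and EIF1AY 1 count, a ratio of 854 (95% counting interval 153 to 33771), so their log2 values depend on the prior count.

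The genes differing between stented high-flow and stented static vessels were set against the sex of the animals, since Y-linked counts were 0 in the static libraries. Low-flow and high-flow vessels differ likewise in Y-linked counts. Over 436 of these genes 78.9% of signs were shared. The median ratio of the unstented difference to the stented one was 0.240 (95% interval 0.209 to 0.283). Picking genes by the stented difference can lower it, so sex stays open. Adipose tissue in stented static replicate 1 was set to need an excess over replicate 2 of at least 0.5 of the fall, the same bar as for sex. Ratios were 0.298 (0.241 to 0.365) over lower genes and 0.145 (0.0912 to 0.181), in the matching direction, over higher ones. Calls favour close replicates, which can lower both. Without that library the calls went from 257 to 59 lower and from 181 to 36 higher. The folds moved less, to 0.820 (95% interval 0.764 to 0.861) of their size over the lower genes and 0.922 (0.894 to 0.942) over the higher ones, as median standard errors went from 0.47 to 0.50 and from 0.46 to 0.56. Without static replicate 2 calls rose, so their loss on both sides leaves adipose tissue open. Flow itself, the difference the design names, also stays open, as does what the d suffixes 3 and 7 in the labels mark, which was not tested.

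Adipocyte and cardiomyocyte markers stood high in single libraries. All 15 adipocyte markers were higher in stented static replicate 1 than in replicate 2 and all 9 cardiomyocyte markers were higher in native replicate 1 than in replicate 2, a smaller share of 100%. These libraries were picked for this pattern, so surrounding tissue carried on some vessels stays open. The lower native adipocyte mean minus the highest cultured one was -1.21 log2 CPM, but this rests on stented static replicate 1 alone, and the other cultured libraries stood at 2.29 to 4.54. A loss of adipocytes in culture stays open too.

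Lower contractile transcripts in culture were set against a lower smooth muscle cell share, which alone would raise all other cell type markers alike. Macrophage and Schwann cell marker medians moved apart by at least 2.59 log2 units (95% interval 1.25 to 4.73, low-flow against native), which argues against it as the only change. A scaling factor moves all genes of a library alike and leaves the gap between contractile and all genes within it unchanged. The lower native gap minus the highest cultured one was 1.92 log2 CPM, above the native range of 0.58, which argues against scaling as the cause of lower contractile transcripts relative to other genes. The change of scaling moved the list median by at most 0.0315 and the median of all genes by at most 0.0286, too little to decide by itself. A lower share or a change of smooth muscle cells stays open, as do untested differences between animals.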

How the results depend on the processing

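A group named alone here is compared with native. DESeq2 called 3092 genes in stented static, 2902 in low-flow, 1368 in stented high-flow against stented static, 105 in low-flow against high-flow and 6 in stented high-flow against high-flow. At an adjusted p under 0.01, stricter by construction, edgeR called 596 in stented static, 1684 in stented high-flow, 771 in high-flow, 550 in low-flow, 60 in stented high-flow against stented static and 10 in low-flow against high-flow. Without a filter it called 1003 in stented high-flow against stented static and 54 in low-flow against high-flow, and with at least 10 counts in every library 2 in the latter. With only the groups compared it called 4884 in low-flow and 32 in stented high-flow against stented static. With the libraries of a single count table it called 1232 in stented static, 3854 in high-flow, 3363 in low-flow, 160 in stented high-flow against stented static and 46 in low-flow against high-flow. The 924 shared genes became 284 at 0.01 and 1441 with DESeq2. Without Y-linked genes, an alternative added after the data were seen, stented high-flow against stented static had 435 and low-flow against high-flow 11. Apart from the stricter threshold, the cause was not tested.

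With a library left out, a lone sample is assumed to vary like the other groups. The counts then ranged from 514 to 1671 in stented static, 1542 to 4072 in stented high-flow, 752 to 1318 in high-flow, 361 to 556 in low-flow, 95 to 784 in stented high-flow against stented static, 5 to 13 in low-flow against high-flow and 0 to 1 in stented high-flow against high-flow, and the shared genes from 283 to 297. The cardiac myosin MYH6 in stented static vessels ranged from -7.83 to 0.50, turning without native replicate 1. In stented high-flow against high-flow the camera adjusted p ranged from 4.24e-19 to 0.971 for interferon response, 0.000776 to 0.792 for hypoxia and glycolysis and 3.08e-08 to 0.921 for cholesterol biosynthesis, with the direction turning without high-flow replicate 1, replicate 2 and replicate 1. For contractile genes in low-flow against high-flow it ranged from 8.01e-07 to 0.919, turning without high-flow replicate 1. In high-flow against native fry gave the erythrocyte and platelet markers an adjusted p of 0.00273, downward. The cause was not tested.

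Replicate numbers were not used as pairs, since their correlations were -0.350 to 0.183, with 2 of 10 pairs above 0.1. A replicate block gave 2489 genes in stented high-flow against native and 185 in stented high-flow against stented static. Of 527 named-gene results, 480 past the threshold, 218 kept it under every alternative except DESeq2 and limma-voom. With single libraries left out 1593 kept their side, 702 were weaker, 4 stronger and 1 turned, MYH6, and 32 of 211 values that had not passed changed sign. With an estimated correlation all 97 list calls were lost and the other 106 lists had not passed before, and with fry 44 no longer passed and 13 newly did. The depth limits calls of genes under a few counts per library.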

Other observations

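The clock output and metallothionein tests below were chosen after the data were seen.

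Circadian clock genes stood lower as a list in every culture. The repressor CRY2 was at 367 and 229 CPM in the native libraries and 11.9 to 22.0 CPM in the cultured ones. Of 11 clock genes 4, 7, 6 and 6 fell in stented static, stented high-flow, high-flow and low-flow vessels against native by edgeR, with median log2 fold changes of -1.44, -1.44, -1.51 and -1.53. The largest camera adjusted p of the 4 was 0.000730, and it was 0.194 with an estimated correlation. This is consistent with a fall of clock output in culture, with the time of day of sampling untested.

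The 2 metallothioneins measured, MT1X and MT3, did not rise together in every culture, and the least number called higher by edgeR in a comparison with native was 0. MT1X was at 5.21 and 6.38 CPM in the native libraries, 1269 ± 1383 CPM in stented static vessels and 13.6 to 44.6 CPM in the other cultured libraries. Its log2 fold changes against native were 7.77 (adjusted p = 0.00152) in stented static and, without passing, 2.35, 2.57 and 2.41 in stented high-flow, high-flow and low-flow vessels (0.0521, 0.0622 and 0.0832). MT3 was called lower in the latter 3 groups (0.00185, 0.00460 and 0.0197), at 0 to 0.140 CPM against 1.32 and 2.21 in native.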
